A study of Mus musculus with 6 samples.

How the data were processed

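Single cells of mouse lung, sorted alveolar type II (ATII) cells and the alveolarspheres grown from them, were measured by 10x Genomics droplet sequencing of 3 prime ends with chemistry v3.1 and cell multiplexing tags, per the labels. The labels list 6 libraries, each the only replicate of its group: 3 of expression and 3 of tags. The authors deposited 1 matrix of UMI counts per gene and barcode, unnormalised whole numbers. Per the submitters' processing notes the tools were bcl2fastq and Cell Ranger 6.0.1, and the builds named are GRCm38 and mm10. Their cell calling, doublet removal and assignment of cells to mice are not stated in those notes.

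Each barcode starts with 1 of 3 library tokens. No token matches a title or description in the labels, and 0 features of the matrix are tags, so barcodes were not assigned to a day, age, mouse or treatment. The tokens are called libraries A, B and C in the order in which they first appear, which says nothing of their group, and the whole matrix is treated as 1 sample. Comparisons of IL-4 with its carrier, of old with young and of day 13 with day 0 were planned only for barcodes that map to the labels and were not run. The tag libraries were not used here.

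Gene IDs were matched to symbols in the GENCODE annotation of GRCm38, which named 52403 IDs. The 233 others hold 0.0209% of UMIs, and 74 symbols belong to several IDs. Cells were kept with at least 1000 UMIs, at least 500 genes and at most 15% of UMIs from 37 mitochondrial genes, which removed 1 barcode of library B and 43 of library C. Doublets were scored in each library by the method of Scrublet, written anew, with 2 simulated doublets per cell and an expected share of 5%. It called 0, 1 and 2 cells of libraries A, B and C, 0.00821% of cells. Whether the method failed here or doublets had been removed before deposition was not tested, and the alternative of removing the highest 5% of scores in each library was added.

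Counts per cell were scaled to a common total and log-transformed, and 2000 variable genes were scaled with a limit of 10 and reduced to 30 principal components. The genes of 16 pathway lists were kept out of this step, and so were genes on even lines of the gene file other than cell type markers. The genes kept out are thus not compared between clusters they defined. Cells were clustered by the Leiden method (leidenalg 0.10.2, igraph 0.11.9) on a graph of shared neighbours among the 20 nearest, at resolution 0.6 with seed 1, which gave 9 clusters. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-image 0.26.0, and edgeR 4.0.16 in R 4.3.3 for TMM factors. Figures were drawn with matplotlib 3.10.9.

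The gene lists, 20 lists of cell type markers, the filters, the clustering settings, the size rule, the rule for naming genes and most of the other settings tried were fixed before the data were examined. The rule that turns markers into cluster names was not: 4 versions were written in turn, each after seeing the clusters that the version before had named. Each cluster was set against the other cells of the same library, in every library with at least 50 of its cells. In version 4, which is used, a marker counts only with a log2 fold of at least 1. A cluster takes the class with the most such markers among its 50 leading genes, if they are at least 3. No other class may have more among the 10 leading genes, and for a class other than ATII, ATII must have fewer there. A cluster without such a class is ATII-like if at least 14 of the 16 ATII markers reach 20 CPM and hold more counts than any other list, unless another class has 2 or more such markers among the 10 leading genes and ATII has fewer. Names end in -like because they rest on transcripts alone.

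Versions 1 and 2 counted markers of any fold and allowed a tie with any class. They named 7165 cells ATI-like and 6935 cells of library A airway secretory-like. Versions 3 and 4 gave the same classes at the settings used. Version 3 allowed no tie among the 10 leading genes and lost the transitional-like name in 5 of 9 alternative settings. Version 4 allows a tie with a class other than ATII, so its keeping of that name in 9 of 9 settings follows in part from how it was written.

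For each comparison of classes, counts were summed over the cells of a class, scaled to counts per 1000000 (CPM) and compared as a log2 fold with a pseudocount of 1 CPM. No test was run, since per the labels each library is the only replicate of its group and libraries B and C are not replicates of each other. Genes pass the size rule with an absolute log2 fold of at least 1 and at least 20 CPM in either class. Intervals are 95% exact Poisson intervals for CPM, exact conditional intervals of the ratio of counts, without the pseudocount, for folds, and exact binomial (Clopper-Pearson) intervals for shares of cells. They cover counting error only, since cells are not replicates. A count of 0 allows up to 3 counts of the total. The median log2 fold of a list is given with its percentile among 10000 random lists matched on mean expression in 25 bins, which is not a p-value.

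The plan was to sum each class over all cells, with a mean over libraries of equal weight as an alternative. Library A held 2 transitional-like and 17 proliferating-like cells but 16348 of the 26381 ATII-like cells, so that sum sets 1 library against others. After this was seen, each of libraries B and C was compared within itself, list medians and named genes were taken from the mean of both libraries, and the planned sums are given beside them. Named genes are up to 4 members of each list with the largest absolute log2 fold, the 6 highest and 6 lowest genes of the even lines that were kept out of the clustering and have at least 50 CPM in either class, and Il4ra, Il13ra1, Il2rg and Stat6. Not every gene the rule names is printed, and 1 of them is not reported here; those printed were picked from them after their values were seen, as were the markers named as examples and the genes named because 5 or fewer of a list passed. Of the 60 list genes the rule names for transitional-like cells, 32 are also named from the sum over all libraries, and of 63 for proliferating-like cells 26 are; of the 6 lowest genes 0 are shared in either comparison, and of the 6 highest 3 and 4 are.

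The size rule was tested on simulated sums at the depths of these classes. Only genes with at least 50 CPM in ATII-like cells were used, above the 20 CPM of the rule. Log2 folds of 2 and 1.5, up or down, put into 50 genes each passed in 100% of genes for the transitional-like and proliferating-like comparisons. Unchanged genes passed in 0%. For cluster 3 in library C, folds of -2 and -1.5 passed in 98% and 92%. The simulation held counting error only, so it says nothing of calls caused by variation between cells, mice or treatments. In 300 of 1500 simulated cells of library C, 100 genes with at least 50 CPM were raised by a log2 fold of 2. These genes lay on lines open to the clustering, and all cells were otherwise drawn from the same profile. The clustering put 100% of cells on the right side. So large a change is easily found, and the result says nothing of how stable the clusters of the real cells are. Alternatives changed the UMI minimum, the mitochondrial limit, the clustering resolution, the number of principal components, the clustering genes, the treatment of doublets, the scaling, the pseudocount, the depth per cell (thinned to 1500 UMIs, which left out 103 transitional-like, 29 proliferating-like and 149 ATII-like cells), the naming rule, the library and the reference cells.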

Results

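The study asked how alveolar type II (ATII) cells of young and old mice respond to interleukin 4 (IL-4), a type 2 cytokine. ATII cells make lung surfactant and are the stem cells of the alveolar epithelium. Per the labels, single-cell RNA was sequenced from 3 expression libraries, with 1 library per group: freshly sorted cells of young and old mice on day 0, cultured cells of young and old mice on day 13, and cultured cells of young mice on day 13. Another 3 libraries held the multiplexing tags that mark which cells came from which mouse or treatment. The culture grew alveolarspheres, hollow balls of epithelium, with the cytokine at 10 ng/ml or its carrier from day 3. The title names IL-4, while the design text gives another interleukin number.

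Barcodes in the matrix carried 3 library tokens that matched no label, and 0 tag features were among its genes. The libraries are called A, B and C here, and their day, age and treatment are unknown. No comparison of IL-4 with its carrier, of old with young mice or of day 13 with day 0 was made. Shares of classes and levels of some genes are listed for each library, but no fold or test of 1 library against another was computed. The matrix is treated as 1 pooled sample without replicates, so intervals are 95% exact intervals that cover counting error only, and no p-value is given. The comparisons below set classes of cells against each other within libraries B and C.

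Of the barcodes in the matrix 36537 were kept and 47 removed. Library A gave 16367 kept cells with a median of 3749 unique molecular identifiers (UMIs) per cell and 63658436 UMIs in total. Library B gave 5592 cells with a median of 8348.5 UMIs and 48660905 in total. Library C gave 14578 cells with a median of 3340.5 UMIs and 53308229 in total.

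Cells named ATII-like were 72.2% of all kept cells (26381 of 36537, exact binomial interval 71.7 to 72.7%). The share was 43.1% and 33.6% under naming rules 1 and 2, earlier versions of the rule used, and 49.7% in libraries B and C together (10033 of 20170, interval 49.0 to 50.4%). Sftpc (ENSMUSG00000022097, chromosome 14, 70520949 to 70524081, minus strand, GRCm38), which encodes surfactant protein C, held 255076 counts per 1000000 (CPM) in library A, 128794 in library B and 116225 in library C. Cells named proliferating-like, led by mitosis genes such as Nusap1, Cenpf, Aurkb and Top2a, were 11.0% of all cells (4009, interval 10.7 to 11.3%). Cells named transitional-like, led by Gm3776, S100a6, Gsta1 and Ndrg1 and holding the markers Sprr1a, Lgals3 and Krt19 among their leading genes, were 7.21% (2633, interval 6.94 to 7.48%).

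The share of each class is given for each library as a value of that library. ATII-like cells made up 99.9% of library A, 10.6% of library B (interval 9.81 to 11.4%) and 64.8% of library C (interval 64.0 to 65.5%). Transitional-like cells numbered 2 in library A, and were 12.2% of library B (interval 11.3 to 13.1%) and 13.4% of library C (interval 12.8 to 13.9%). Proliferating-like cells numbered 17 in library A, and were 16.7% of library B (interval 15.7 to 17.7%) and 21.0% of library C (interval 20.3 to 21.7%). Unnamed cells were 0 of 16367 in library A, which allows a share of up to 0.0225%, 60.5% of library B (interval 59.2 to 61.8%) and 0.892% of library C (interval 0.746 to 1.06%). Of the unnamed cells 3347 in library B and 129 in library C were in cluster 3, in which 16 of 16 ATII markers reached 20 CPM and summed to 182859 CPM, against 173445 and 165757 CPM in the ATII-like clusters 1 and 4. Naming rule 1 called cluster 3 ATII-like, so the share of ATII-like cells in library B depends on the rule.

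**Figure D1:**
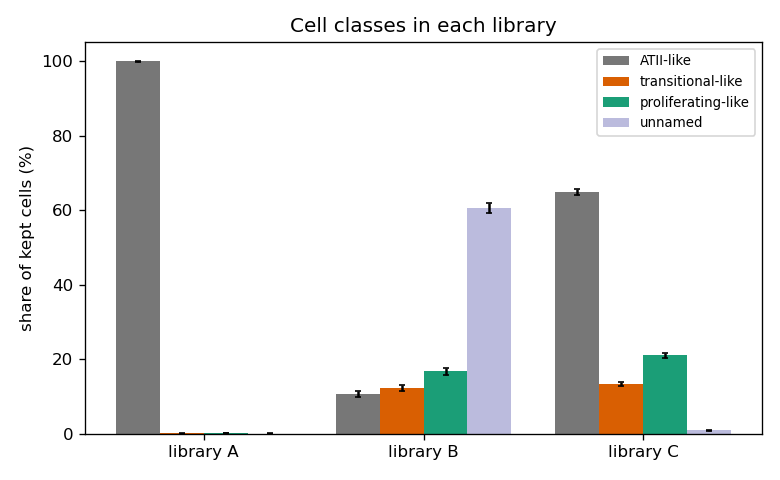
Share of kept cells in each class (percent, vertical axis) for libraries A, B and C; bars are the shares and whiskers their 95% exact binomial intervals. The ATII-like bar is at 99.9% in library A, 10.6% in library B and 64.8% in library C, and the unnamed bar in library B, nearly all cluster 3 with ATII markers, is at 60.5%.

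The ATII-like class joined 4 clusters. Clusters 0 and 2 held cells of library A and of no other library, and clusters 1 and 4 held cells of libraries B and C apart from 1 cell. The name rests on the abundance of the ATII markers, of which 15 or 16 of 16 reached 20 CPM in each of these clusters, and not on the genes that lead each cluster. Those leading genes were Scin, Cpe and Lncpint in cluster 0, Rnase4, Lyz2 and Lrp2 in cluster 1, Sprr1a, S100a6 and Scgb1a1 in cluster 2, and Dlk1, Gm13183 and Bpifb1, a goblet marker, in cluster 4. The 10 leading genes held 0 ATII markers with a log2 fold of at least 1 in clusters 0, 2 and 4 and 1 in cluster 1. The 10 leading genes of cluster 2 held both airway secretory markers Scgb1a1 and Cyp2f2, of which Cyp2f2 had a log2 fold under 1 and did not count, and naming rules 1 and 2 called this cluster airway secretory-like. The ATII-like class held 528 cells of cluster 1 and 65 of cluster 4 in library B, and 6636 and 2804 in library C. Cluster 3, with 3347 cells of library B and 129 of library C, was led by the secretoglobin gene Scgb1a1, Slc2a3, Il4i1 and Scgb3a1 and stayed unnamed. The 2 airway secretory markers among its 10 leading genes, Scgb1a1 and Scgb3a1, kept it from the ATII-like name. They held 123 and 33.7 CPM in its library B cells, beside 137580 CPM for Sftpc. In its library C cells they held 347 and 90.2 CPM, beside 106513 CPM for Sftpc.

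No cluster was named alveolar type I (ATI)-like, so the planned comparison of ATI-like with ATII-like cells has no value. Cluster 1 held 3 ATI markers, Akap5, Ager and Cldn18, among its 50 leading genes. It had 1 ATI and 1 ATII marker among the 10 leading genes, and this tie left it ATII-like. Naming rules 1 and 2, which allowed such a tie, called it ATI-like. ATI cells are the thin cells of gas exchange, and 9 of 16 ATI markers reached 20 CPM in each library. Hopx, an ATI marker, held 9.03 CPM in library A, 42.0 CPM in library B and 116 CPM in library C. At clustering resolution 1.2, in place of 0.6, a cluster of 928 cells was named ATI-like, with 137 cells in library B and 789 in library C. Against ATII-like cells it had log2 folds of 3.94 and 2.33 for Ager, 3.73 and 3.11 for Hopx and 4.17 and 3.45 for Cav1 in libraries B and C. Of these cells 511 were in the ATII-like class and 415 in the transitional-like class as reported, so both classes held cells with ATI markers. No marker of goblet, basal, neuroendocrine, dendritic, neutrophil, T or NK, fibroblast, smooth muscle or pericyte, or erythroid cells reached 20 CPM in any library.

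Markers of some other lists did pass 20 CPM in a library. Among ciliated markers 3 of 10 did so in library A, where Sec14l3 was highest at 82.6 CPM. Among monocyte or interstitial macrophage markers Apoe, a lipid carrier, held 555 CPM in library A, and Ly6c2 held 21.5 CPM in library B. Among endothelial markers Pecam1 held 88.7 CPM in library A. The B cell marker Cd79b held 25.9, 131 and 144 CPM in libraries A, B and C. Plet1 of the alveolar macrophage list held 22.0, 25.3 and 5.08 CPM, and Krt19 of the mesothelial list, which is also a transitional marker, held 52.0, 276 and 314 CPM. Airway secretory markers summed to 6407, 571 and 697 CPM in libraries A, B and C, of which 5, 4 and 3 of 10 reached 20 CPM.

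Transitional-like cells, which carry markers of the state between ATII and ATI, were compared with ATII-like cells. The treatment and age of each cell are unknown, so the classes may hold different mixes of them. A fold between classes, here and in the comparisons below, cannot be told apart from a difference in that mix. This includes the folds of the IL-4 and inflammatory genes. In library B (682 against 593 cells) and in library C (1949 against 9440 cells), 13 of 21 genes of glycolysis and hypoxia, 11 of 17 of xenobiotic and oxidative stress and 6 of 14 of p53 and senescence were at least 2-fold higher in transitional-like cells. At least 2-fold lower in both were 11 of 15 ATII markers, 5 of 13 inflammatory and 2 of 8 MHC class II genes. Hmox1, the haem-degrading enzyme induced by oxidative stress, stood at 982 against 52.0 CPM in library B, a log2 fold of 4.21 (interval 4.04 to 4.44), and at 797 against 48.5 CPM in library C, a log2 fold of 4.01 (interval 3.96 to 4.12). Retnla, a secreted protein induced by IL-4 (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461, plus strand), stood at 817 against 5518 CPM in library B, a log2 fold of -2.75 (interval -2.81 to -2.70), and at 4063 against 26563 CPM in library C, a log2 fold of -2.71 (interval -2.73 to -2.69). The size of this difference depends on the make-up of the ATII-like class, since Retnla stood at 2144 CPM in cluster 1 and 30088 CPM in cluster 4 of library B, and at 19822 and 39281 CPM in library C. Against cluster 1 alone its log2 folds were -1.39 in library B and -2.29 in library C, and against cluster 4 alone -5.20 and -3.27.

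Of 21 measured glycolysis and hypoxia genes, 13 were at least 2-fold higher in both libraries, 0 were lower and 8 did not pass the size rule in both. Their median log2 fold over the libraries was 1.43, at percentile 100 of random lists of matched expression. Adm, which encodes the vasodilator adrenomedullin, had log2 folds of 4.80 in library B and 4.42 in library C. Bnip3, a hypoxia-induced mitophagy receptor, had 1.77 and 2.52, and the oxygen sensor Egln3 had 1.11 and 2.89. Of 17 xenobiotic and oxidative stress genes, 11 were higher in both libraries and 0 lower (median 1.33, percentile 100). Besides Hmox1 these included the metallothioneins Mt1 (3.06 and 3.29) and Mt2 (4.32 and 3.75) and Gclm (2.87 and 2.36), a subunit of the enzyme that limits glutathione synthesis.

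Of 14 p53 and senescence genes, 6 were higher in both libraries and 0 lower (median 0.99, percentile 100). The cell cycle inhibitor Cdkn2b had log2 folds of 1.92 in library B and 1.64 in library C, and the stress cytokine Gdf15 had 1.99 and 1.44. Of 13 TGF beta and matrix genes, 4 were higher in both libraries and 0 lower (median 1.13, percentile 100; 1.14 in library B and 0.75 in library C). They were Ccn2 (2.17 and 2.12), Plaur (2.22 and 1.89), the urokinase receptor, Tgfb2 (1.43 and 1.11) and Timp2 (1.11 and 1.15). The pooled median of this list was -0.37, of the opposite sign.

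Of 13 inflammatory and acute phase genes, 5 were at least 2-fold lower in both libraries and 1 was higher (median -1.23, percentile 0). Cxcl5, a neutrophil attractant, had log2 folds of -3.88 and -2.81, the alarmin Il33 had -3.09 and -1.62, and Cxcl1 had -1.88 and -1.83. Lrg1 and Lcn2 were the other lower genes, and Cxcl16, with 1.73 and 1.17, was the higher gene. Of 7 measured genes of the IL-4 and IL-13 list, 3 were lower in both libraries and 0 higher (median -1.19, percentile 0.01; -0.55 in library B and -1.40 in library C). They were Retnla, the anion exchanger Slc26a4 (-1.94 and -2.29) and the cytokine signalling suppressor Socs2 (-1.51 and -1.40). Chia1, an acidic chitinase, had -0.30 in library B and -2.09 in library C. Of 8 MHC class II genes, 2 were lower in both libraries and 0 higher (median -0.96, percentile 0), namely H2-Eb1 (-2.28 and -1.62) and H2-Aa (-1.67 and -1.41).

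Unfolded protein response genes went both ways, with 4 of 18 lower and 1 higher in both libraries (median -0.59, percentile 0.01). Ddit3, a stress transcription factor that can drive cell death, was the higher gene (3.28 and 2.61), while the chaperone cofactor genes Sdf2l1 (-1.97 and -1.75) and Creld2 (-1.49 and -1.76), Manf and Pdia6 were lower. Against cluster 1 alone, 0 of these 18 genes were lower in both libraries. Of 14 other surfactant and lamellar body genes, 3 were lower and 1 was higher (median -0.03, percentile 19.0). The lower genes were Lyz2, a lysozyme (-3.36 and -1.66), Dram1 (-2.25 and -1.25) and Lgi3, and the higher gene was the lysosomal protease Ctsd (1.17 and 1.09). Among 20 lipid and cholesterol synthesis genes, 2 were lower, Elovl1 (-2.32 and -1.21) and Acaca (-1.66 and -1.08), and 0 were higher (median -0.26, percentile 8.98).

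The remaining lists each had 2 or fewer genes past the size rule in both libraries. Of 14 dissociation and immediate early genes, which respond to tissue handling, 2 were higher in both libraries and 0 lower (median 0.33, percentile 94.5). They were Dusp1 (2.13 and 1.37) and Ier3 (1.46 and 1.16), and the pooled median was -1.61, of the opposite sign. In the interferon list 1 of 5 genes, Ifitm3 (-2.19 and -1.45), was lower in both libraries (median -1.13, percentile 0.095; -2.19 in library B, -0.07 in library C and a pooled median of 0.11), and Isg15 had -2.20 in library B and -0.07 in library C. In the list of Wnt, Notch, YAP and FGF signalling 2 of 10 genes were lower, Sp5 (-2.26 and -1.28) and Id2 (-1.27 and -1.05), while the median was 0.23 (percentile 86.4; pooled median -0.40). Of 21 oxidative phosphorylation genes 0 passed the size rule in both libraries (median -0.20, percentile 1.5; pooled median 0.41), with Cycs at -0.64 and -0.74. The only measured cell cycle gene, Tyms, had -1.15 and -0.57, and of 3 genes of the intestinal or ectopic list 0 passed (median -0.32, percentile 13.1), with the lung lineage factor Nkx2-1 at -0.96 and -0.50.

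The marker lists were used to name the clusters, and many of their genes, unlike those of the lists above, also to cluster the cells, so their counts describe the classes and do not test them. Of the markers named next, Sftpa1 and Emp2 were not used for clustering. Of 15 measured ATII markers, 11 were lower in both libraries (median -1.54), with Sftpa1 at -2.27 and -2.05 and Slc34a2, a phosphate transporter, at -3.31 and -1.80. Of 15 transitional markers, 10 were higher (median 1.95), with Lgals3 at 3.15 and 3.09 and Krt19 at 2.51 and 2.46. Of 9 ATI markers, 4 were higher (median 1.10), namely Hopx (1.98 and 1.66), Clic5 (1.60 and 1.59), Emp2 and Timp3. Both measured mesothelial markers were higher, Krt19 and Msln (3.81 and 3.86). Of the other marker lists, 0 of 4 airway secretory, 0 of 1 proliferating, 0 of 1 B cell and 0 of 1 endothelial markers passed in both libraries. The nuclear RNA Malat1, a sign of RNA quality, had log2 folds of 1.37 in library B and 0.92 in library C, beside the higher glycolysis and stress genes.

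Only genes on even lines of the gene file, kept out of the clustering and with at least 50 CPM in either class, were ranked next. Of these the 6 highest were Gm3776, Adm, Hmox1, Mt2, Phospho1 and Mt1. The 6 lowest were Hdc, Rbpjl, Lrg1, Noxo1, Cd14 and Il33. Gm3776 had 571 counts in transitional-like and 0 in ATII-like cells of library B, and a log2 fold of 6.02 in library C. Hdc, the enzyme that makes histamine, had -3.85 and -2.57, and Cd14, the co-receptor for bacterial lipopolysaccharide, had -2.75 and -2.04. Across all genes measured, 274 were at least 2-fold higher and 152 at least 2-fold lower in both libraries.

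In library B alone 486 genes were higher and 488 lower, in library C alone 352 were higher and 190 lower, and the log2 folds of the libraries had Pearson's r of 0.896 across genes, which are not independent replicates. Cells of both libraries were clustered together and genes used for clustering were included, so part of this likeness was built in. The same holds for r and the counts over all genes in both libraries in the comparisons below. Summed over all libraries, as planned, 590 genes were higher and 1236 lower. That sum sets transitional-like cells of libraries B and C against ATII-like cells of which 16348 of 26381 came from library A, so it mixes the classes with the libraries. Its list medians not given above were 2.34 for glycolysis and hypoxia, 1.94 for xenobiotic and oxidative stress, 0.70 for p53 and senescence, -1.09 for IL-4 and IL-13, -0.91 for inflammatory, -0.90 for MHC class II, -0.76 for unfolded protein response, -0.48 for other surfactant and lamellar body, -1.60 for lipid and cholesterol synthesis, -0.28 for intestinal or ectopic and -0.05 for cell cycle. For markers they were -2.48 for ATII, 1.80 for transitional, 0.65 for ATI, 4.08 for mesothelial, -5.67 for airway secretory, 1.69 for proliferating, 0.03 for B cell and 0.35 for endothelial lists. Scaling by trimmed means (TMM) moved the median log2 fold of all genes by 0.15 in the sum, 0.20 in library B and -0.02 in library C, and gave 804 higher and 1031 lower, 682 higher and 296 lower, and 338 higher and 207 lower.

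Cluster 3, 59.9% of library B, was left out of every reference within libraries. In library B Lyz2 stood at 106 CPM in transitional-like cells and 107 CPM in cluster 3, and Isg15 at 12.0 and 5.19 CPM. The lower level of these genes thus depends on the reference, while Retnla (817 and 14415 CPM) and Slc34a2 (57.2 and 464 CPM) were lower here too. Other reference cells within libraries B and C changed some of these counts. Of 59 named genes past the size rule in both libraries, 49 stayed past it against cluster 1 alone, without Sdf2l1, Creld2, Manf, Pdia6, Tgfb2, Timp2, Ctsd, Sp5, Lcn2 and Emp2. Against cluster 4 alone 55 did, without Slc26a4, Lgi3, Lyz2 (0.40 in library B and -0.57 in library C) and Acaca (0.62 and -1.13), and without the cells named ATI-like at resolution 1.2 56 did, without Gdf15, Acaca and Timp2. Against cluster 1 alone 235 genes were higher and 128 lower in both libraries, 0 of 18 unfolded protein response genes were lower and 2 of 13 TGF beta and matrix genes were higher. Against cluster 4 alone 436 genes were higher and 210 lower, Isg15 had a mean log2 fold of 1.03 over the libraries, and the medians of the other surfactant and lamellar body (0.34), lipid and cholesterol (0.01) and intestinal or ectopic (0.03) lists, and of airway secretory (0.65) and endothelial markers (0.31), were above 0. Without those ATI-like cells, in either class, 289 genes were higher and 225 lower, with 14 of 21 glycolysis and hypoxia genes higher (median 1.61) but 5 of 17 xenobiotic and oxidative stress (median 1.08) and 4 of 14 p53 and senescence genes (median 0.77).

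**Figure D2:**
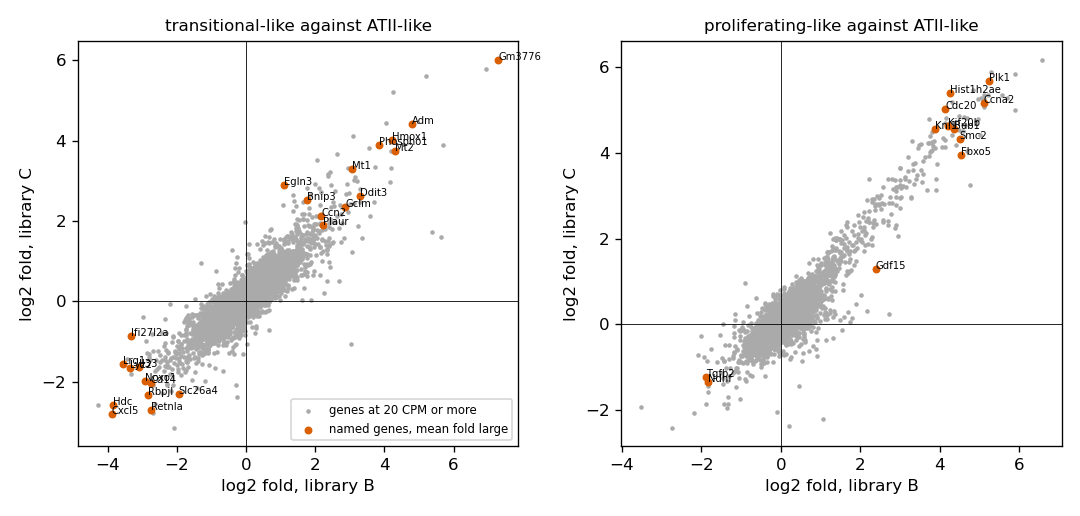
Log2 fold of CPM in library B (horizontal axis) against library C (vertical axis), for transitional-like (left) and proliferating-like (right) against ATII-like cells. Each grey point is a gene at 20 CPM or more in either class and orange points are named genes with large folds; Hmox1 lies at 4.21 and 4.01 on the left and Plk1 at 5.25 and 5.67 on the right.

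The comparison of proliferating-like with ATII-like cells asks what the dividing cells express besides the cell cycle. In library B (933 against 593 cells) and in library C (3059 against 9440 cells), 18 of 18 measured cell cycle genes were at least 2-fold higher (median log2 fold 2.70, percentile 100). Plk1, a mitotic kinase, had 90.7 against 1.42 CPM in library B and 88.0 against 0.754 CPM in library C, log2 folds of 5.25 and 5.67. The S and G2 phase cyclin Ccna2 had 5.11 and 5.17, the anaphase activator Cdc20 had 4.14 and 5.02, and the spindle checkpoint kinase Bub1 had 4.36 and 4.57. These genes were kept out of the clustering, but the class was named from other genes of mitosis.

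Of 11 p53 and senescence genes, 2 were higher in both libraries and 0 lower (median 0.50, percentile 99.6), Gdf15 (2.39 and 1.30) and the p53 target Phlda3 (65.6 against 27.9 CPM in library B, and 1.02 in library C). In the unfolded protein response list 1 of 17 genes was higher, asparagine synthetase Asns (1.68 in library B, and 112 against 47.8 CPM in library C; list median 0.31, percentile 98.8). In the inflammatory list 1 of 14 was lower, Il33 (-1.35 and -1.33), while Cxcl5 had 1.01 and 0.78 (list median 0.19, percentile 80.8). In the TGF beta and matrix list 1 of 10 was lower, Tgfb2 (-1.87 and -1.22; list median -0.22, percentile 0.49).

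The other lists had 0 genes past the size rule in both libraries. Among 7 IL-4 and IL-13 genes (median 0.20, percentile 74.5; 0.29 in library B and -0.24 in library C), Retnla had 0.90 in library B (interval 0.88 to 0.93) and -0.37 in library C (interval -0.37 to -0.36), and Chia1 had -0.10 and -2.05. The direction for Retnla depends on the reference: it had 2.27 and 0.06 against cluster 1 alone, and -1.54 and -0.93 against cluster 4 alone. Among 20 lipid and cholesterol synthesis genes (median 0.26, percentile 93.0; pooled median -1.07), the fatty acid enzymes Elovl1 (-1.43 and -0.84) and Scd1 (-1.31 and -0.82) were past the rule in library B. The 14 other surfactant and lamellar body genes had a median of -0.29 (percentile 0), with Lyz2 at -1.86 and -0.85. The 5 interferon genes had a median of -0.34 (percentile 0.97), with Isg15 at -2.08 and -0.72, and the 8 MHC class II genes had -0.12 (percentile 7.01), with Cd74 at -0.39 and -0.18.

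Medians close to 0 were found for 19 glycolysis and hypoxia genes (0.06, percentile 52.4; -0.10 in library B and 0.32 in library C), 17 xenobiotic and oxidative stress genes (0.08, percentile 38.8), 21 oxidative phosphorylation genes (0.12, percentile 93.8), 14 dissociation and immediate early genes (0.00, percentile 16.9; pooled -1.86), 9 genes of Wnt, Notch, YAP and FGF signalling (-0.17, percentile 0.86) and 3 intestinal or ectopic genes (0.11, percentile 57.6; pooled -0.10). Cytochrome c, encoded by Cycs, had 0.86 and 0.71.

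Among marker lists, 14 of 14 proliferating markers were higher in both libraries (median 5.02), with Top2a at 4.69 and 4.82. Of 9 ATI markers, 6 were lower (median -1.38), with Hopx at -2.19 and -2.07, Akap5 at -3.51 and -1.93 and Ager at -1.85 and -1.58. This direction depends on the reference, since against cluster 4 alone 0 of the 9 were lower in both libraries (median 0.66). In the sum over all libraries Hopx and Akap5 were lower at -1.05 and -1.08, but had 1.16 and 1.13 under naming rule 2, which takes clusters 1 and 2 out of the ATII-like class. Of 15 ATII markers 0 passed in both libraries (median -0.39), with Sftpc at -0.37 and -0.41. Of 13 transitional markers 1, the cell cycle inhibitor Cdkn1a, was higher (1.63 and 1.15), and its pooled log2 fold was -1.07. Of 4 airway secretory markers, 1 B cell, 1 endothelial and 1 mesothelial marker, 0 passed. Only genes on even lines of the gene file, kept out of the clustering and with at least 50 CPM in either class, were ranked next. Of these the 6 highest were Plk1, Hist1h2ae, Kif20b, Smc2, Fbxo5 and Knl1. The 6 lowest were Ndnf (-1.84 and -1.35), Il33, Ociad2 (-1.21 and -1.14), Ypel3, Elovl1 and Rasl11a.

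In all, 285 genes were at least 2-fold higher and 27 at least 2-fold lower in both libraries, with Pearson's r of 0.927 between the libraries' log2 folds across genes. Library B alone gave 377 higher and 73 lower, library C alone 347 and 45, and the sum over all libraries, which has the same mixture as above, 781 and 1077. Its list medians not given above were 3.16 for cell cycle, 1.22 for glycolysis and hypoxia, 0.90 for IL-4 and IL-13, 0.86 for oxidative phosphorylation, 0.46 for p53 and senescence, 0.41 for inflammatory, 0.30 for unfolded protein response, 0.24 for xenobiotic and oxidative stress, -0.20 for interferon, -0.30 for Wnt, Notch, YAP and FGF, -0.31 for MHC class II, -0.41 for TGF beta and matrix and -0.43 for other surfactant and lamellar body. For markers they were 5.97 for proliferating, -1.29 for ATI, -1.21 for ATII, 0.00 for transitional, -5.22 for airway secretory, 0.71 for B cell, 0.12 for endothelial and 0.57 for mesothelial lists. TMM scaling moved the median log2 fold of all genes by 0.04 in the sum, -0.06 in library B and -0.18 in library C, and gave 853 higher and 1014 lower, 346 higher and 87 lower, and 283 higher and 77 lower.

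Some medians of these lists differed by more than 1.5 times between libraries B and C. They were 0.10 and 0.31 for lipid and cholesterol synthesis, 0.10 and 0.24 for inflammatory, -0.53 and -0.17 for interferon, -0.23 and -0.09 for MHC class II, -0.26 and -0.12 for Wnt, Notch, YAP and FGF, -0.01 and -0.12 for TGF beta and matrix, 0.18 and 0.06 for xenobiotic and oxidative stress, 0.02 and -0.03 for dissociation, 0.03 and 0.19 for intestinal or ectopic genes and -0.54 and -0.17 for ATII markers.

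Cluster 3 was left out of the reference within libraries here too. In library B Retnla stood at 10814 and 8383 CPM in the proliferating-like clusters 5 and 7, and at 14415 CPM in cluster 3. Ager stood at 104 and 134 against 63.0 CPM, so both directions turned, while Hopx, at 12.6 and 19.0 against 20.9 CPM, stayed lower. Against cluster 1 alone 310 genes were higher and 40 lower in both libraries, and against cluster 4 alone 280 and 15. Of 23 named genes past the size rule in both libraries 23 stayed past it against cluster 1 alone, 14 against cluster 4 alone, where Phlda3, Asns and Ypel3 were among those lost, and 22 without the cells named ATI-like at resolution 1.2, where Ypel3 was lost. Several of the lower genes were higher against cluster 4 alone, with mean log2 folds over the libraries of 1.42 for Hopx, 0.62 for Akap5, 0.66 for Ager, 1.07 for Lyz2, 0.76 for Isg15, 1.88 for Tgfb2, 2.05 for Ndnf and 0.25 for Ociad2, while Cxcl5 had -0.21. List medians of the opposite sign against cluster 4 alone were those of IL-4 and IL-13 (-0.60), unfolded protein response (-0.07), TGF beta and matrix (0.70), other surfactant and lamellar body (0.07), inflammatory (-0.02), oxidative phosphorylation (-0.09) and Wnt, Notch, YAP and FGF genes (0.18), and of the ATI (0.66, with 0 of 9 lower in both libraries), mesothelial (0.41) and endothelial markers (0.20). Against cluster 1 alone they were those of dissociation (-0.02) and intestinal or ectopic genes (-0.03) and of transitional (-0.14) and B cell markers (0.19).

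**Figure D3:**
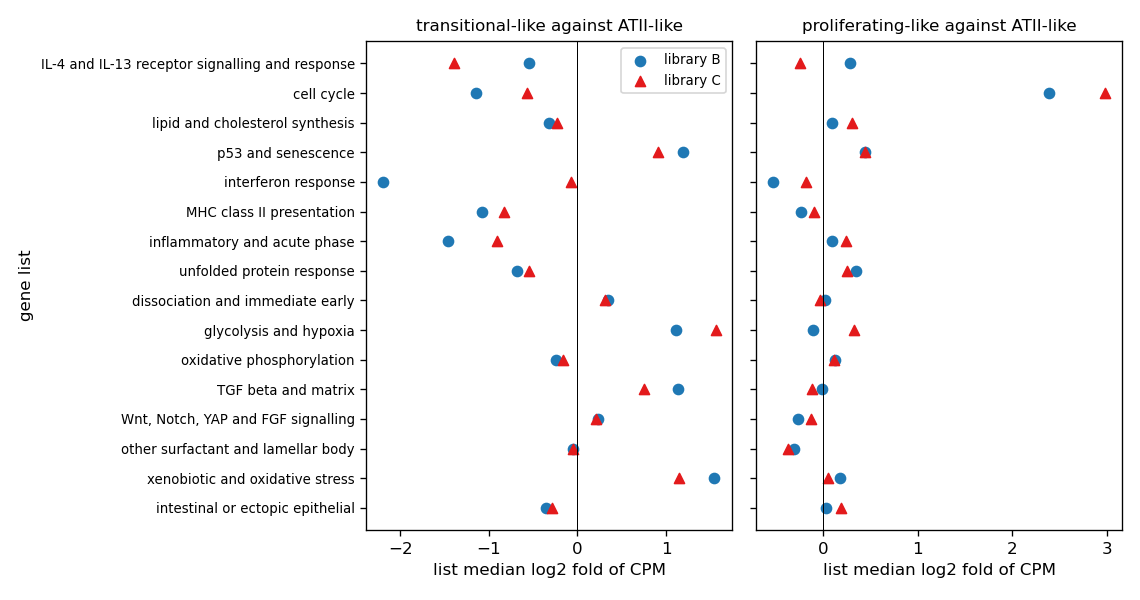
Median log2 fold of CPM of each pathway list (horizontal axis), in library B (circles) and library C (triangles), for transitional-like (left) and proliferating-like (right) against ATII-like cells. Glycolysis and hypoxia is at 1.11 and 1.56 on the left, and cell cycle is at 2.39 and 2.98 on the right.

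The receptor of IL-4 was measured at levels under the 20 CPM of the size rule. Il4ra (ENSMUSG00000030748, chromosome 7, 125552120 to 125579474, plus strand), the subunit that binds IL-4, held 9.02 CPM in library A (exact Poisson interval 8.29 to 9.79), 12.7 CPM in library B (11.7 to 13.7) and 16.3 CPM in library C (15.2 to 17.4). Il13ra1, which pairs with it in epithelium, held 14.2, 14.6 and 12.2 CPM, and the signal transducer Stat6 held 25.5, 8.57 and 8.44 CPM. Il2rg, the partner subunit in blood cells, had 0 counts in each library, which allows up to 0.0471, 0.0617 and 0.0563 CPM. In transitional-like cells Il4ra stood at 4.36 against 17.7 CPM in library B and 12.3 against 18.6 CPM in library C, and in proliferating-like cells it stood at 10.1 and 12.7 CPM. Il13ra1 stood at 18.3 against 12.3 CPM in library B, a log2 fold of 0.54 (interval 0.03 to 1.12), and at 16.2 against 11.5 CPM in library C, a log2 fold of 0.46 (interval 0.15 to 0.82), in transitional-like cells. In proliferating-like cells it stood at 11.6 and 12.0 CPM.

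Retnla varied between cells of the same library. With every cell thinned to 1500 UMIs, the 10th, 50th and 90th percentiles of its UMIs per cell were 0, 11 and 41 in library B (5579 cells) and 0, 21 and 85 in library C (14298 cells). In library A, 99.5% of 16367 thinned cells had at most 1 Retnla UMI (interval 99.4 to 99.6%).

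**Figure D4:**
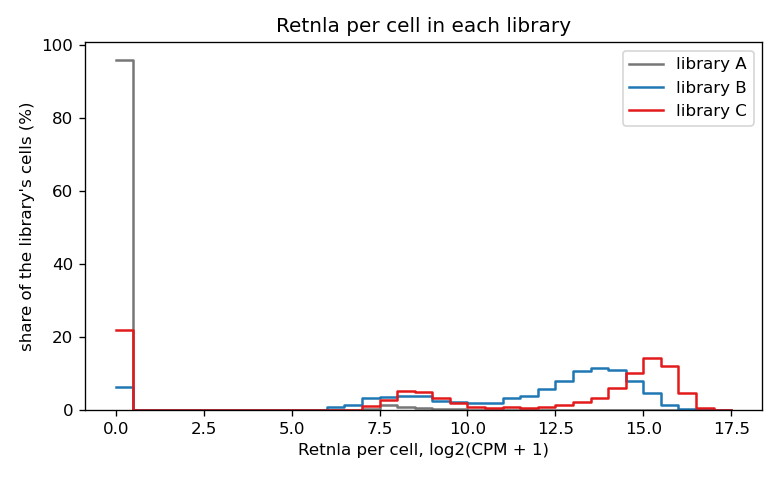
Retnla per cell as log2 of CPM plus 1 (horizontal axis) against the share of the cells of each library (percent, vertical axis), before thinning; each line is a library. The lines of libraries B and C have a high peak, cells without a Retnla UMI lie at 0 and cells with 1 or a few UMIs, a level at which free RNA was not measured, lie between; the line of library A is almost all at 0.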

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

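The tests of naming rules 1 to 3, of libraries B and C alone, of the highest doublet scores, of cluster 3 in the reference, of cluster 1 or 4 alone as reference and of leaving out cells named ATI-like at resolution 1.2 were chosen after the results were seen; the others were planned. Intervals for shares cover counting error only, so most changes of the clusters move them. The share of ATII-like cells, 72.2% as reported, was 43.1% and 33.6% with naming rules 1 and 2, 59.5% and 70.0% with at least 500 and 3000 UMIs per cell, 71.0% and 74.4% at resolutions 0.3 and 1.2, 62.4% with 15 principal components, 75.7% with all variable genes, 70.9% with predicted doublets kept and 73.3% without the highest 5% of doublet scores. For transitional-like cells, 7.21% as reported, it was 5.60% with at least 3000 UMIs, 8.50% and 5.86% at resolutions 0.3 and 1.2, 7.56% with all variable genes, 8.63% with doublets kept and 6.89% without the highest scores. For proliferating-like cells, 11.0% as reported, it was 12.2% with at least 3000 UMIs, 9.06% at resolution 1.2, 7.72% with all variable genes and 10.5% without the highest scores. ATI-like cells, 0 as reported, were 19.6% with naming rule 1 and 19.6% with rule 2, 13.2% with at least 500 UMIs, 2.54% at resolution 1.2 and 9.92% with 15 principal components. Airway secretory-like cells, also 0, were 19.0% with rules 1 and 2 and 8.96% with all variable genes. Unnamed cells, 9.62%, were 0.104% with rule 1, 12.2% with at least 3000 UMIs, 8.11% at resolution 1.2 and 0.109% with all variable genes. With at least 500 UMIs 36553 cells were clustered and with doublets kept 36540, against 36537 as reported. Shares that moved in those settings did so because nearly the same cells were divided otherwise, not because of the few cells added. Why the clusters changed was not tested. Under naming rule 3 the transitional-like name is lost in 5 of 9 alternative settings, and rule 4, written after that was seen, keeps it in 9 of 9 by allowing a tie.

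Counts of genes past the size rule, summed over all libraries, stayed within 1.5 times the reported count under the other alternatives. Transitional-like cells had 590 higher genes, against 352 in library C alone, and 1236 lower genes, against 283 for the mean of libraries, 488 in library B and 190 in library C. With cluster 1 and cluster 4 alone as reference of the mean, they had 358 and 911 higher and 269 and 382 lower genes, and without cells named ATI-like at resolution 1.2 the mean had 463 lower genes. Proliferating-like cells had 781 higher genes, against 338 for the mean, 377 in library B and 347 in library C, and 1077 lower genes, against 41, 73 and 45. Their values were 390 higher genes with cluster 1 alone, and 73 and 34 lower genes with cluster 1 and cluster 4 alone, and 336 higher and 35 lower without those ATI-like cells. Here the sum holds library A in its reference and the alternatives leave it out by construction.

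Of 1694 values for 77 named genes of the transitional-like comparison 6 reversed, and of 1056 for 48 genes of the other 26 did; these genes are a subset picked after values were seen. Klf6 in transitional-like cells had -1.89 in the sum and 1.04 for the mean, 1.32 in library B, 0.77 in library C, 1.01 and 1.18 with cluster 1 and cluster 4 alone, and 1.04 without the ATI-like cells. In proliferating-like cells Cdkn1a had -1.07 in the sum and 1.39, 1.63, 1.15, 1.30, 2.02 and 1.43, and Dnajb1 had -1.99 and 0.39, 0.41, 0.37, 0.35, 0.55 and 0.41, in the same order. Hopx, -1.05 in the sum, had 0.61 and 1.16 with naming rules 1 and 2 and 0.14 with 15 principal components, and Akap5, -1.08 in the sum, had 0.78 and 1.13 with these rules; in those settings an ATI-like cluster leaves the reference, and under rules 1 and 2 so does cluster 2. With cluster 4 alone as reference these had 1.42 and 0.62, and Cxcl5 (-0.21), Lyz2 (1.07), Ndnf (2.05), Ociad2 (0.25), Ager (0.66), Btg2 (0.33) and Fgfr2 (0.99) also had the sign opposite to their sum; the cause was not tested.

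The limit of 5% mitochondrial UMIs removed no cell and says nothing of stability. ATI-like against ATII-like cells has no reported value, so its alternatives were left out. The alternatives planned for IL-4, age and day (DESeq2, no filter on low counts, a replicate block, leaving out each mouse, at least 3000 UMIs) could not be run without a map of barcodes to mice, and no paired analysis was possible because no barcode maps to a mouse. Genes under 20 CPM such as Il4ra are not called by the size rule.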

Other observations

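The comparison of cluster 3 and the tests of cytosolic RNA loss, doublets, shallow cells, macrophages, tags and gene length were chosen after the results were seen. The tests of surfactant counts and of depth were written down before their results.

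Cluster 3, unnamed and with 3347 of its 3476 cells in library B, was compared with ATII-like cells. Against the 593 ATII-like cells of library B and, with 129 cells, the 9440 of library C, 47 genes were at least 2-fold higher and 24 at least 2-fold lower in both libraries, with Pearson's r of 0.488 across genes. The secretoglobin genes Scgb1a1 (log2 folds 4.07 and 3.17) and Scgb3a1 (3.18 and 2.86) and the glucose transporter gene Slc2a3 (3.70 and 3.69), which were used for clustering, were among the higher genes. Of 6 airway secretory markers 2, Scgb1a1 and Scgb3a1, passed the size rule in both libraries, with a list median of 0.05 and Hp at -4.19 and -0.59. Of 14 transitional markers 4 were higher, Sprr1a (2.71 and 1.52), Fn1 (2.35 and 2.39), Nupr1 (2.55 and 1.54) and Cdkn1a (1.11 and 1.35), with a list median of 0.27 (percentile 99.8); these too were used for clustering, and 4 were higher against cluster 1 alone and 5 against cluster 4 alone. Of 8 IL-4 and IL-13 genes 0 passed the size rule in both libraries, with a list median of 0.66 (percentile 100) and Retnla at 1.39 and 0.45. Outside the lists, Il4i1, an amino acid oxidase, had 1.26 and 2.18, and Chil4, a chitinase-like protein, had 1.98 and 1.66; both were used for clustering and chosen after their values were seen. In the inflammatory list C3, Ccl20 and Relb were higher in both libraries, and Saa3 had -5.54 and -2.13 without 20 CPM in either class of library C. ATI markers were lower for 4 of 9, such as Ager (-2.64 and -2.55), and Sftpc had -0.18 and -0.33. Of 16 ATII markers 2 were lower, Lyz1 (-3.77 and -1.06) and Muc1 (-1.83 and -1.36), and 1 was higher, Hc, and of 14 other surfactant and lamellar body genes 2 were lower, Lyz2 (-3.34 and -1.94) and Acot1 (-1.37 and -1.44). These values depend on the reference, of which 528 of 593 cells in library B were in cluster 1: of 16 genes that passed in both libraries, those named here other than transitional markers, with the ATI markers Hopx and Akap5, 15 did so against cluster 1 alone but 4 against cluster 4 alone, namely Scgb1a1, Scgb3a1, Slc2a3 and Hc. Against cluster 4 alone Retnla had -1.06 and -0.11, Il4i1 -0.24 and 1.19, Chil4 -0.45 and 0.91, Ager -0.34 and -0.11, Lyz1 0.51 and 0.25 and Lyz2 0.42 and -0.86, and the IL-4 and IL-13 median was 0.10 and the ATI marker median 0.86.

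Levels in each library are given as values of unmapped libraries. The genes listed next were not picked by a rule fixed beforehand. Retnla held 27.4 CPM in library A, 11752 in library B and 22528 in library C, and Chil4 held 0.110, 8886 and 2020. The lysozyme gene Lyz2 held 33575, 234 and 145 CPM, and Hc, complement component C5, held 1372, 35.4 and 13.2. The immediate early genes Jun (2192, 257 and 251 CPM) and Fosb (742, 27.7 and 23.6), the heat shock gene Hspa1a (1138, 23.0 and 20.1), the glycolytic enzyme gene Gapdh (299, 5399 and 6255) and the iron-binding protein gene Lcn2 (1027, 10432 and 8015) are further values. With other settings a cluster was named ATI-like: 4832 cells with at least 500 UMIs per cell, 928 at resolution 1.2 and 3624 with 15 principal components, of which 200, 137 and 55 cells were from library B.

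The higher glycolysis and stress genes of transitional-like cells are the first pattern. Fewer surfactant counts, which raise the share of every other gene, cannot be the whole cause: without the ATII markers in the totals the glycolysis median was 1.24, against 1.43 with them. Doublets would hold more UMIs, but the median UMI count of transitional-like cells was 0.736 times that of ATII-like cells in library B and 0.883 times in library C. This argues against a class made mostly of doublets of ATII-like cells. A median cannot show whether doublets make up a smaller part of the class, so that stays open. Damaged cells that lost cytosolic RNA would show a glycolysis median below the fold of nuclear Malat1; it was below by 0.26 in library B (difference -0.264) and above by 0.642 in library C, so this stays open. Per the labels each expression library has a single day. Day is then the same on both sides of a comparison within a library, if each token is 1 of these libraries. Age and treatment were not tested, as they are unknown, so the pattern is not called biological.

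Retnla differed widely between cells of the same library, which is the second pattern. Shallow cells do not account for this, since 40.0% of library C cells thinned to 1500 UMIs had at most 1 Retnla UMI, against 7.08% for the ATII gene Cxcl15, which has fewer counts. Macrophages, which express Retnla, would bring their markers, but the alveolar macrophage markers together held 8.76 CPM in library C. A mixture of treatments or ages within a library may underlie it and cannot be tested, since 0 tag features are in the matrix.

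Clusters 0 and 2 of library A, the third pattern, differed in transcripts of long genes. Over 2651 genes kept out of the clustering, the median log2 fold of cluster 0 against cluster 2 was 0.70 in the longest 25% of genes (74558 bases or more) and -0.19 in the shortest 25% (up to 10388 bases), a difference of 0.888. Malat1, a nuclear RNA, stood at 26478 CPM in cluster 0 and 7523 CPM in cluster 2. A difference in depth is argued against, since 98.5% of the length difference was left among 6076 cells of each cluster matched on UMIs in 50 bins, with medians of 3597 and 3595.5 UMIs against 3972 and 3459 before. A candidate explanation is a larger share of nuclear or unspliced RNA in cluster 0, which the length difference goes with but which intronic reads, not used here, would test; no biological explanation was tested.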
